A study of Mus musculus with 30 samples.

How the data were processed

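Bacteria in stool of female Gpr15l-deficient (KO) and wild-type (WT) mice were measured by 16S rRNA gene amplicon sequencing in 30 libraries, 5 for each genotype at weaning, after co-housing and after re-separation. Per the labels' protocols, DNA was extracted from stool with a silica column kit, the V4 region was amplified by PCR and paired ends were read on an Illumina sequencer. The deposited values are whole-number counts of reads per sequence variant and library, not normalized, each variant with a taxon name from kingdom to genus. The submitters' processing notes name R 4.5.1 and limma without a role. The name of the deposited counts points to DADA2 as the denoising tool. Its version and settings, the taxonomic reference and any filter on reads or variants are not given in the sources used here. The variants come without their sequences, so a variant is identified by its row in the table, and a genus name rests on the authors' classification of a short region. Variants of one genus can be strains, species or copies of the gene within a genome, and counts of reads follow the number of 16S copies and the yield of PCR as well as the number of cells.

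The table held 3697 variants, of which 2744 had no reads in the 30 libraries, and all 30 columns of counts were used. Of the others, 485 had reads in the 20 weaning and co-housing libraries, 468 in the 10 re-separation libraries and 0 in both, so the 2 sets were treated as separately processed. The 4 variants named as mitochondria were left out of all totals and tests but the check of non-stool reads, which left 483 and 466 bacterial variants. Genera were summed from variants by genus name, or by the lowest name given above it, and 94.9% of bacterial reads had a genus name. Libraries held 10560 to 73776 reads. Group means were 23189 ± 10232 (KO) and 29919 ± 15045 (WT) at weaning, 26956 ± 9702 and 30383 ± 8747 after co-housing, and 59667 ± 4577 and 54890 ± 13065 after re-separation (SD, n = 5). No library repeated another: over the 60 pairs of libraries within groups, chi-square per degree of freedom was 36.1 to 344, where sampling noise alone gives about 1. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

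Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3; glmQLFit with robust estimation, glmQLFTest, TMMwsp scaling factors) with 1 coefficient per group, so that groups share an estimate of the spread, and with Benjamini-Hochberg adjustment at a threshold of 0.05. Features needed at least 10 reads in at least 3 libraries, which left 292 variants in the weaning and co-housing set, 278 in the re-separation set and 71 genera over all 30 libraries. Log2 fold changes are given with their standard errors. Where all libraries of a group had 0 reads, the fold is a lower bound against a floor of 3 counts per library, and no fold is given where the other group lies at or under that floor. Only 5 counts in the 30 libraries were equal to 1. If low counts were removed earlier, 0 reads may hide more than 3 counts, and these bounds would be too high. Contrasts compared the genotypes at each time, the times within each genotype and, as interactions, the genotype difference between times.

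Composition was compared on Bray-Curtis distances of proportions, with the R2 of genotype or time from a permutational test over all 126 splits of 5 against 5 libraries (exact; smallest p 0.00794), and changes of the genotype difference with distance-based redundancy analysis (vegan 2.7.1, 99999 permutations of residuals). Richness is the expected number of variants at 10491 reads, the smallest library, and the Shannon index uses natural logarithms. Single values per library were compared with exact two-sided permutation tests over 252 orderings. Benjamini-Hochberg adjustment ran over the 3 times for composition and each diversity measure, over the 4 time comparisons for composition, over the 3 interactions, over the 6 lists of a time or a genotype and over all tests of non-stool reads. The carry-over score is the mean centred log-ratio (pseudocount 0.5) of features higher in KO at weaning minus that of features lower in KO at weaning. Restricted variants were found, after rarefying to 10491 reads with seed 1, in at least 3 of 5 mice of one genotype and in 0 of the other. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps.

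The 6 taxon lists were the order Bacteroidales; butyrate-forming Clostridia (Roseburia, Oscillibacter, Butyricicoccus, Intestinimonas, Lachnoclostridium, Anaerotruncus, [Eubacterium] groups and related genera); lactic acid bacteria and bifidobacteria; mucus or epithelium associated genera (Akkermansia, Mucispirillum, Helicobacter, Candidatus Arthromitus); Proteobacteria with Desulfobacterota; and the order Erysipelotrichales. Lists of mitochondria, chloroplast, reads without a kingdom, skin genera and genera common in reagents served as a check of non-stool reads. Groups, tests, lists, alternatives and the rule for named taxa were fixed before the data were examined, except where the text says that a choice was made after. The rule took, for each genotype contrast, up to 10 variants and 10 genera higher and as many lower with the largest fold among those past the threshold with reads in at least 4 of 5 mice of the higher group, up to 5 for each interaction and time contrast, the 3 with the smallest p where fewer than 3 passed, the 10 leading families and genera, the 5 leading variants, and list members at 1% or more in any group.

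The plan had foreseen variant tests over all 30 libraries. Since no variant had reads in both sets, variants were fitted within each set, every comparison that spans the sets used genera, and restricted taxa after re-separation used full taxon strings. The tests of genera over time and of their interactions, and those of lists and diversity over time, were added after the data were seen. The alternatives were 2 other scalings, DESeq2 1.42.0, limma-voom (limma 3.58.1), other filters, a fit of only the groups compared, other distances and feature levels, other settings of the diversity, carry-over and restriction measures, and leaving out each library in turn, with 4 libraries (1, 5, 11 and 19) left out together as a choice made after seeing the data.

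The edgeR step was tested on simulated counts drawn from the fitted means, dispersions and library sizes (20 sets per contrast). At the fitted spread it found 0.75% of 4-fold, 7.37% of 16-fold and 41.8% of presence-or-absence changes among 292 variants for genotype at weaning, 10.0%, 43.4% and 70.0% among 278 variants for genotype after re-separation, and 11.0%, 62.0% and 77.5% among 71 genera for genotype at weaning. False calls were 11.6%, 4.01% and 8.16% of all calls in these 3 comparisons, and 14.2% for 292 variants after co-housing. With the dispersion scaled by 0.1, 38.8%, 68.7% and 59.7% of the same changes were found among variants at weaning. Simulated sets for KO against WT at weaning without a difference (483 variants) had a composition p under 0.05 in 5 of 200 and richness p under 0.05 in 11 of 200, and the composition test found an exchange of 20 leading variants in 200 of 200.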

Results

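Stool bacteria were profiled by sequencing of the V4 region of the 16S rRNA gene, a marker carried by all bacteria, in female mice lacking Gpr15l (KO) and in wild-type (WT) mice. Gpr15l encodes a peptide secreted by epithelial cells of the gut and skin, the ligand of the lymphocyte receptor GPR15. Stool was taken at weaning at 4 weeks of age, after 4 to 5 weeks in cages that mixed the genotypes (co-housing), and after 6 further weeks in which the genotypes were kept apart again (re-separation). The design asks whether a difference between the genotypes at weaning is kept when the mice share cages, where they eat each other's faeces, and whether it is there after they are parted. Each of the 6 groups held 5 libraries, numbered 1 to 5 (KO) and 6 to 10 (WT) at weaning, 11 to 15 (KO) and 16 to 20 (WT) after co-housing, and 21 to 25 (KO) and 26 to 30 (WT) after re-separation. Libraries held between 10560 and 73776 reads, with 10560 to 52398 in the 20 weaning and co-housing libraries and 39735 to 73776 in the 10 re-separation libraries. The labels give no cage or litter and do not follow a mouse from one time to the next, so p-values measure only the spread between these samples. Bacterial 16S reads hold no read of Gpr15l, so the genotype of each library rests on its label.

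The table listed sequence variants, each with a taxon name. Of its variants, 485 had reads in the weaning and co-housing libraries and 468 in the re-separation libraries, and 0 had reads in both. Variants were therefore compared only within each set of libraries, and comparisons that reach into the re-separation libraries used genera, 79 of which had reads in both sets. In these comparisons time and library set cannot be told apart. A variant is named by its genus and its row in the table.

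Prevotellaceae and Muribaculaceae, families of the order Bacteroidales that degrade polysaccharides, made up the largest shares of bacterial reads over the 30 libraries, with means of 21.5% and 19.8%. Lachnospiraceae, anaerobic Clostridia, followed with 12.3%, Mycoplasmataceae, which lack a cell wall, with 11.8%, and Helicobacteraceae, spiral bacteria of the mucus layer, with 8.36%. Rikenellaceae (4.92%), Bacteroidaceae (4.35%), Oscillospiraceae (3.17%), Sutterellaceae (2.31%) and Deferribacteraceae (1.98%) completed the 10 leading families, which held 86.0% to 95.5% of the reads of a group on average. The leading genera were Prevotellaceae UCG-001 (20.3%), unnamed Muribaculaceae (18.8%), Mycoplasma (11.0%), Helicobacter (8.36%), the Lachnospiraceae NK4A136 group (7.43%), Bacteroides (4.35%), Alistipes (3.60%), unclassified Lachnospiraceae (2.57%), Parasutterella (2.31%) and Mucispirillum (1.98%). The leading variants were Prevotellaceae UCG-001 rows 22 (13.1%) and 615 (6.14%), Mycoplasma rows 12 (7.87%) and 580 (3.10%) and Helicobacter row 836 (2.92%).

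At weaning, Akkermansia, a degrader of mucin, was found in 5 of 5 KO mice at 1.54% ± 2.35 of bacterial reads (SD, n = 5) and in 1 of 5 WT mice, with a group mean of 0.00212% ± 0.00474, a log2 fold change of 8.34 ± 1.57 (SE; edgeR adjusted p = 0.000177). Library 1 held 5.68% and the other 4 KO libraries 0.0705% to 1.02%. Gastranaerophilales, non-photosynthetic relatives of the Cyanobacteria, were higher in KO mice at 2.40% ± 1.69 against 0.162% ± 0.209 (log2 fold change 3.04 ± 0.95). Blautia, an acetate-forming member of the Lachnospiraceae, stood at 0.347% ± 0.540 against 0.00596% ± 0.0133 (log2 fold change 5.07 ± 1.35), with 1.26% in library 1 and 0 reads to 0.414% in the other 4 KO libraries. Unclassified Tannerellaceae were at 0.934% ± 1.94 against 0.0277% ± 0.0278 (log2 fold change 4.03 ± 1.5), with 4.40% in library 1 and at most 0.0940% in the other 4 KO libraries. Without library 1 the KO mean was 0.0682% and the log2 fold change 0.69. The Rikenellaceae RC9 gut group was lower in KO mice, with 0.0349% ± 0.0353 against 1.00% ± 0.484 (log2 fold change -5.44 ± 1.08). Odoribacter, a short-chain fatty acid producer, was lower with 0.236% ± 0.139 against 1.25% ± 1.05 (-3.32 ± 0.81), and Ureaplasma with 0.349% ± 0.210 against 1.36% ± 1.13 (-2.65 ± 0.92). Clostridia UCG-014 had 0 reads in KO mice and 0.15% ± 0.157 in 4 of 5 WT mice, at least 9.60-fold higher in WT and 5.94-fold without library 8. Unclassified Erysipelotrichaceae had 0 reads in KO mice and 0.0505% ± 0.0365 in 4 of 5 WT mice, at least 3.23-fold higher. Without library 1 the KO mean was 0.506% for Akkermansia and 0.118% for Blautia, with log2 fold changes of 7.23 and 3.76. Without library 8 the WT mean was 0.0687% for Gastranaerophilales (4.18) and 0.812% for Odoribacter (-2.80). All 4 were still called.

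Across the 71 genera tested, 17 differed between the genotypes at weaning, 6 higher and 11 lower in KO mice (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). An unadjusted p under 0.05 was found for 26 genera. Of the 17, 7 were called under all 18 alternative settings, 3 more under each of the 17 settings in which they passed the filter, and 0 turned in direction. With library size in place of the composition-corrected scaling, 26 genera were called, 16 higher and 10 lower, and that scaling moved the median log2 fold change by 0.75. Fitting only the 2 weaning groups, where fewer genera pass the filter, called 8. The call of unclassified Tannerellaceae was lost without library 1, 6, 7, 8, 9 or 10, and that of Ureaplasma without library 2, 3 or 7 and under both other scalings.

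**Figure D1:**
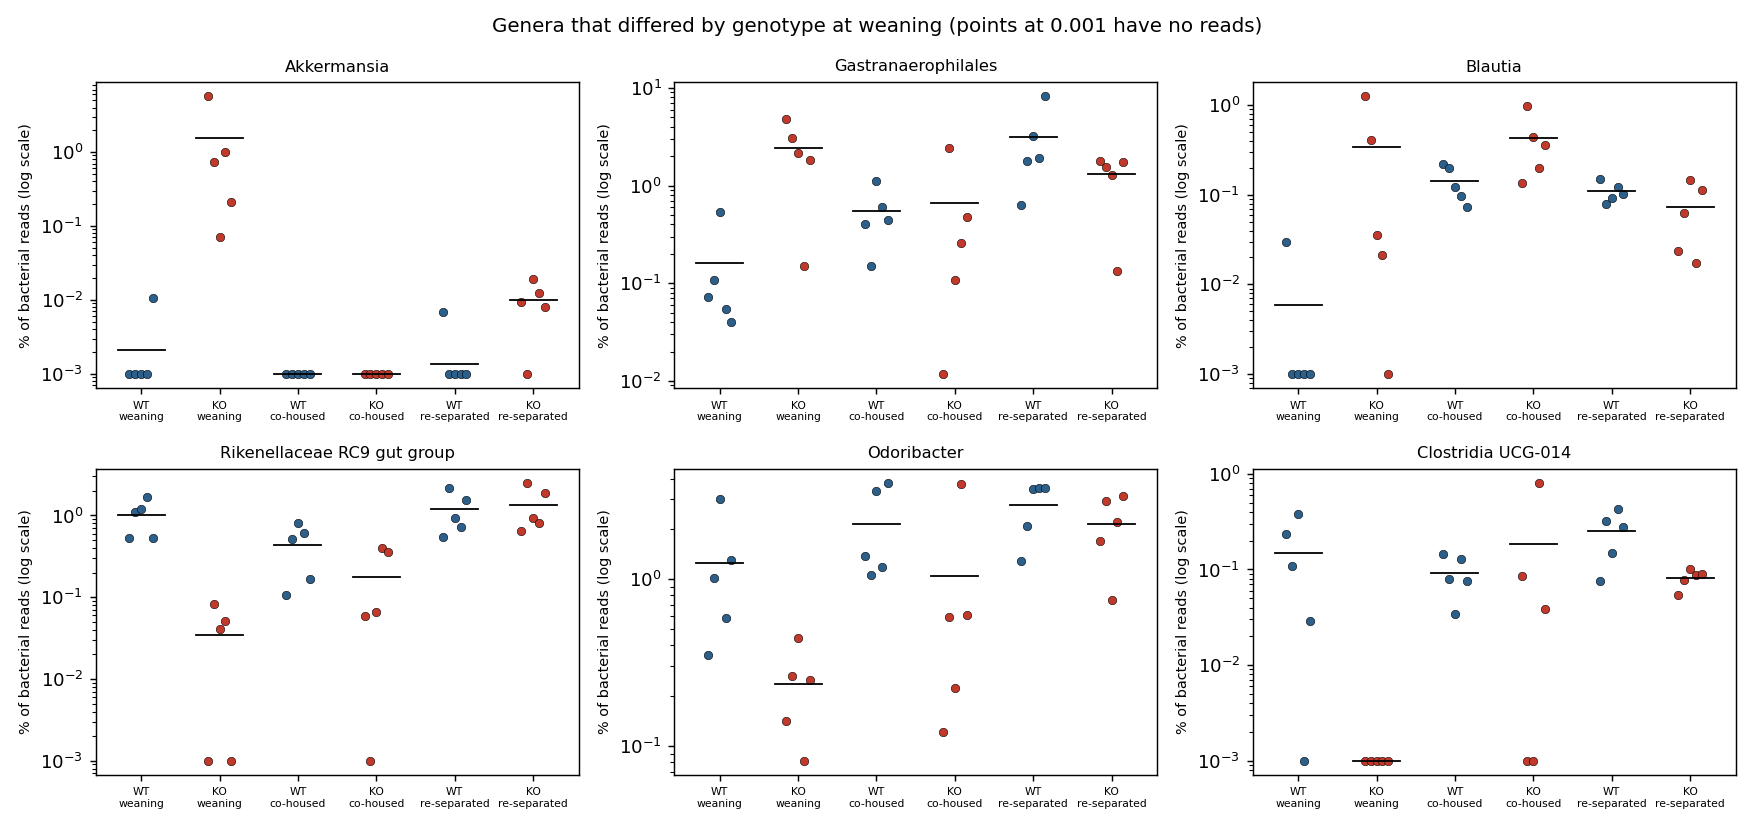
Relative abundance (percent of bacterial reads, log scale) of Akkermansia, Gastranaerophilales, Blautia, the Rikenellaceae RC9 gut group, Odoribacter and Clostridia UCG-014 in each of the 30 libraries, by genotype (KO red, WT blue) and time. Points are libraries, bars are group means, and points at 0.001 have no reads. Akkermansia had reads in all 5 KO weaning libraries, in 1 WT weaning library and in no KO library after co-housing.

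At weaning, 58 of the 61 variants that differed by genotype had 0 reads in one of them (edgeR). In data simulated at the fitted spread, the test found 41.8% of presence-or-absence changes but 7.37% of 16-fold changes. Calls thus favour variants absent from a genotype, and the 58 do not show that most differences were of this kind. Prevotellaceae UCG-001 row 25 had reads in 5 of 5 KO mice, 3.73% ± 7.00, and 0 reads in WT mice (at least 309-fold higher; edgeR adjusted p = 0.000493). Library 1 held 16.2% and the other 4 between 0.230% and 0.999%, and without library 1 the bound was 50.03-fold. By contrast, row 26 of the same genus had 0 reads in KO mice and 0.762% ± 0.275 in 5 of 5 WT mice (at least 48.7-fold higher in WT). Rikenella row 42 was at 0.258% ± 0.174 in KO mice only (at least 21.3-fold), and Rikenella row 41 at 0.296% ± 0.251 in WT mice only (at least 18.9-fold, 12.5-fold without library 9). Other variants of these 2 genera were shared: Prevotellaceae UCG-001 row 22, at 18.1% ± 12.6 in 4 of 5 KO and 31.4% ± 3.53 in 5 of 5 WT mice (edgeR adjusted p = 0.397), and Rikenella row 143, at 0.419% ± 0.308 and 0.262% ± 0.113 in 5 of 5 of each (edgeR adjusted p = 1), were not called; these 2 were chosen after their values were seen. Further variants with reads in KO and none in WT mice were Gastranaerophilales row 168 (1.88% ± 1.80, at least 156-fold, 96.7-fold without library 1), unclassified Lachnospiraceae row 282 (1.12% ± 0.907, at least 92.8-fold) and Muribaculaceae row 60 (0.627% ± 0.697, at least 51.9-fold, 29.3-fold without library 2). Clostridia vadinBB60 row 181 (at least 23.9-fold, 11.2-fold without library 1), Oscillibacter row 470 (at least 13.3-fold, 8.61-fold without library 3), ASF356 row 238 (at least 11.2-fold) and a Roseburia variant (at least 6.98-fold, 4.38-fold without library 5) also had 0 reads in WT mice. The call of row 470 was lost without library 3, 6, 8 or 9, that of row 238 without library 2, 3 or any of 6 to 10, and that of the Roseburia variant without any one of the 10 libraries. Variants with reads in WT and none in KO mice were Bacteroides row 48 (2.43% ± 2.10, at least 155-fold), Alistipes row 137 (1.26% ± 1.06, at least 80.7-fold, 50.5-fold without library 7) and Odoribacter row 97 (0.703% ± 0.647, at least 44.9-fold, 29.0-fold without library 8). The same held for Muribaculaceae rows 112 (0.476% ± 0.164, at least 30.4-fold) and 69 (at least 14.3-fold), and NK4A136 group rows 291 (0.372% ± 0.319, at least 23.8-fold, 15.2-fold without library 7) and 246 (at least 12.7-fold, 7.32-fold without library 8). The call of row 291 was lost without library 3 or 5.

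Of the 292 variants tested, 61 differed by genotype at weaning, 20 higher and 41 lower in KO mice (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). An unadjusted p under 0.05 was found for 124. Lachnospiraceae accounted for 9 of the 20 and 17 of the 41. The count fell to 27 without library 3, 36 without library 5, 38 without library 6 and 37 without library 8, and limma-voom called 37. Of the 61, 12 were called under every alternative setting. Libraries 1, 5, 11 and 19 stood apart from their groups, and without them 15 variants were called, 14 of them among the 61.

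Composition as a whole also differed by genotype at weaning. On Bray-Curtis distances genotype took 23.4% of the variation, against 11.1% on average over all 126 splits of the 10 libraries. The exact permutation p was 0.00794, the smallest these splits allow, and 0.0238 after Benjamini-Hochberg adjustment over the 3 times. With counts summed to families R2, the share of the variation, was 0.1598 and the call was lost (exact permutation p = 0.190). The mean distance between genotypes was 0.5215, which exceeded the average of the 2 within-genotype means by 0.0766 ± 0.0265 (jackknife SE). KO mice lay farther from each other (mean distance 0.575) than WT mice did (0.315), and farther than they lay from WT mice. The permutation test can respond to unequal spread too, so its p does not show a shift of composition alone. The expected number of variants at 10491 reads was 111 ± 33.1 in KO and 135 ± 29.7 in WT mice (SD, n = 5; exact permutation p = 0.365). The Shannon index was 3.33 ± 0.218 and 3.23 ± 0.170 (exact permutation p = 0.437). The inverse Simpson index, which gives more weight to the leading variants, was higher in KO mice by 3.10, with 9.68 to 13.8 in KO and 6.24 to 9.37 in WT libraries (exact permutation p = 0.00794, unadjusted). Of the 6 taxon lists fixed in advance, none passed adjustment at weaning by the exact permutation test with all libraries. Without library 4, 3 passed: Bacteroidales (56.0% ± 17.2 in the other KO mice; adjusted p = 0.0238) and Erysipelotrichales (0 reads; 0.0476) were lower and butyrate-forming Clostridia (1.37% ± 0.780; 0.0238) higher in KO mice. Butyrate-forming Clostridia came closest, at 1.19% ± 0.795 in KO and 0.263% ± 0.158 in WT mice (exact permutation p = 0.0159, adjusted 0.0952). In edgeR 2 of its 25 variants were higher in KO mice, and 0 adjusted over the list alone. Bacteroidales, at 61.1% ± 18.8 and 76.3% ± 6.09 (exact permutation p = 0.0873, adjusted 0.175), held 3 variants higher and 15 lower in KO mice among 79 tested. Adjusted over the list alone the counts were also 3 and 15. The mucus or epithelium list (Akkermansia, Mucispirillum, Helicobacter, Candidatus Arthromitus) was at 8.64% ± 5.74 and 4.42% ± 2.84 (exact permutation p = 0.143, adjusted 0.214), with 1 of 9 variants higher and 1 lower, 2 calls adjusted over the list alone. In that list, Helicobacter was at 5.57% ± 3.20 and 4.21% ± 2.74. Mucispirillum, a resident of the mucus layer, was at 6.50% in library 5 and at most 0.435% in the other 4 KO libraries. Erysipelotrichales were at 0.0175% ± 0.0392 and 0.0762% ± 0.0438 (exact permutation p = 0.0635, adjusted 0.175; 0 of 2 variants called, 2 lower adjusted over the list alone). Lactic acid bacteria and bifidobacteria were at 0.239% ± 0.129 and 0.702% ± 0.646 (exact permutation p = 0.214, adjusted 0.257; 0 of 3 variants, also adjusted over the list alone). Proteobacteria with Desulfobacterota were at 5.96% ± 2.33 and 5.24% ± 3.13 (exact permutation p = 0.683, adjusted 0.683; 0 of 9 variants, also adjusted over the list alone).

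**Figure D2:**
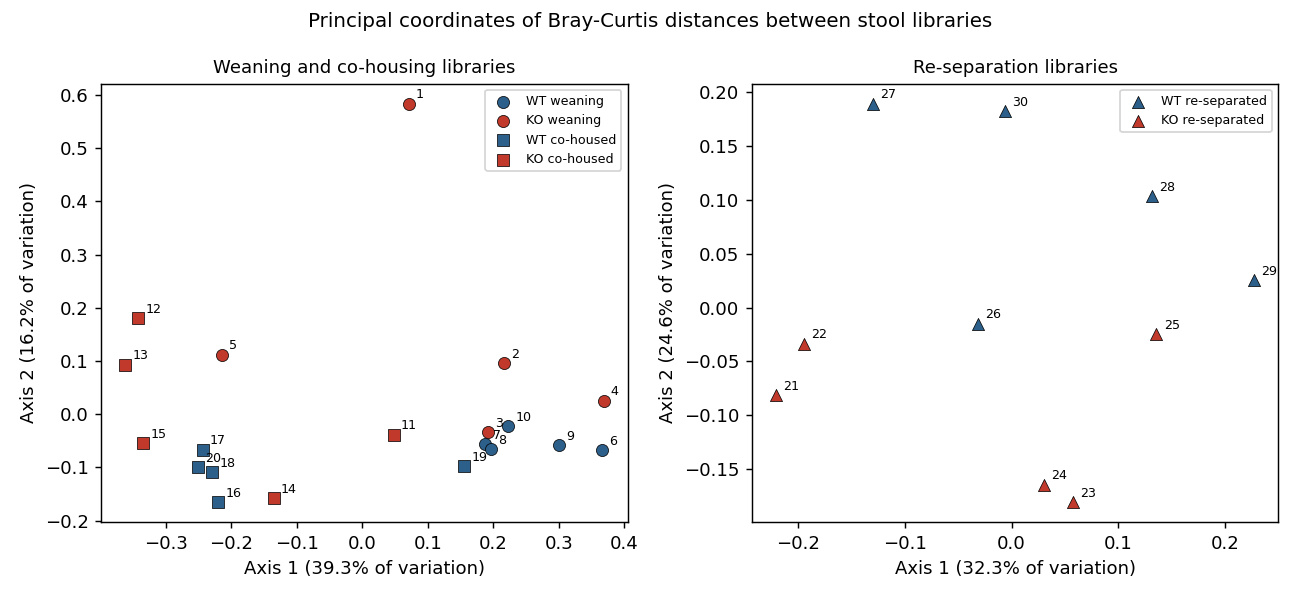
Principal coordinates of Bray-Curtis distances between the 20 weaning and co-housing libraries (left; axes 1 and 2 hold 39.3% and 16.2% of the variation) and between the 10 re-separation libraries (right; 32.3% and 24.6%). Each point is a library with its number, coloured by genotype (KO red, WT blue) and shaped by time. Libraries 5, 11 and 19 lie nearer to the libraries of the other time than to their own.

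From weaning to the end of co-housing, 15 genera rose and 6 fell in WT mice (edgeR). No mice kept apart over these weeks were sampled, so age and co-housing cannot be told apart in either genotype. Unnamed Muribaculaceae fell from 27.2% ± 7.92 to 10.8% ± 8.39 (log2 fold change -2.04 ± 0.61; edgeR adjusted p = 0.0122). Prevotellaceae UCG-001 fell from 32.1% ± 3.31 to 15.8% ± 4.96 (-1.82 ± 0.53), and Bacteroides from 7.10% ± 4.57 to 2.33% ± 2.57 (-2.41 ± 0.73). Parasutterella, a betaproteobacterium that uses little sugar, fell from 4.81% ± 3.00 to 0.510% ± 0.415 (-4.09 ± 0.92). Lactobacillus fell from 0.702% ± 0.646 to 0.10% ± 0.0745 (-3.85 ± 1.05) and Ureaplasma from 1.36% ± 1.13 to 0.202% ± 0.134 (-3.45 ± 0.95). The NK4A136 group rose from 1.88% ± 0.919 to 14.7% ± 8.94 (2.00 ± 0.75) and unclassified Oscillospiraceae from 0.226% ± 0.138 to 3.58% ± 1.81 (3.16 ± 0.83). Mucispirillum rose from 0.169% ± 0.114 to 2.82% ± 1.98 (3.20 ± 0.91) and Oscillibacter from 0.103% ± 0.0713 to 1.39% ± 0.656 (2.82 ± 0.86). Roseburia, a butyrate producer, rose from 0.0206% ± 0.0340 to 0.576% ± 0.571 (3.74 ± 1.09) and Blautia from 0.00596% ± 0.0133 to 0.143% ± 0.0658 (3.77 ± 1.29). Without library 19 the co-housed means were 7.19% for Muribaculaceae (-2.99), 1.21% for Bacteroides (-3.76) and 0.330% for Parasutterella (-5.09). Roseburia changed by 2.99 without library 16 and 5.24 without library 8. Without library 6 Blautia had 0 reads in WT mice at weaning, so the size of its rise is then not measured. The call was lost for Bacteroides without library 9, for the NK4A136 group without library 6, 7, 8, 10, 16 or 20, and for Blautia without library 7, 9 or 10.

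These were 21 of the 71 genera tested (33 with an unadjusted p under 0.05). Library size in place of the composition-corrected scaling gave 26 up and 6 down with the median log2 fold change moved by 0.78, and DESeq2's scaling 12 up and 8 down with the median moved by -0.43. Without library 19, in which Bacteroidales held 66.4% of reads against at most 34.1% in the other 4 co-housed WT libraries, 34 genera were called. Of 292 variants 2 passed in edgeR, with 96 at an unadjusted p under 0.05. Muribaculaceae row 60 rose from 0 reads to 0.523% ± 0.422 (at least 43.3-fold; edgeR adjusted p = 0.0241), and Muribaculaceae row 94 fell from 0.291% ± 0.15 to 0 reads (at least 27.2-fold; edgeR adjusted p = 0.0475). DESeq2 called 33, limma-voom 57, a fit to these 2 groups 32 and edgeR without libraries 1, 5, 11 and 19 called 22. In edgeR the count was 12 without library 19, 0 without library 6, 7, 8, 9, 10 or 16 (81 to 105 with an unadjusted p under 0.05) and 1 without library 17, 18 or 20.

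In KO mice the same interval took Akkermansia from 1.54% ± 2.35 to 0 reads in 5 of 5 co-housed KO mice (at least 125-fold lower, 40.9-fold without library 1; edgeR adjusted p = 4.45e-06). Muribaculum fell from 2.76% ± 3.02 to 0.238% ± 0.0886 (log2 fold change -3.80 ± 0.89) and Parabacteroides from 1.32% ± 1.61 to 0.0886% ± 0.0498 (-3.90 ± 1.02). Unclassified Tannerellaceae fell from 0.934% ± 1.94 to 0.00999% ± 0.0155 (-6.35 ± 1.68; without library 1 the weaning mean was 0.0682% and the change -3.02, not called), Bacteroides from 8.51% ± 5.30 to 1.30% ± 0.949 (-2.85 ± 0.74), and Parasutterella from 4.04% ± 3.16 to 0.637% ± 0.667 (-3.24 ± 0.89). The NK4A136 group rose from 1.97% ± 2.08 to 15.0% ± 3.95 (3.20 ± 0.79), Odoribacter from 0.236% ± 0.139 to 1.05% ± 1.5 (2.17 ± 0.78; without library 14, which held 3.70%, the co-housed mean was 0.386% and the change 0.77, not called). Tuzzerella and the NK4A214 group, both at 0 reads in KO mice at weaning, rose to 0.108% ± 0.0825 (at least 6.89-fold) and 0.0403% ± 0.0307 (at least 2.58-fold). Roseburia went from 0.188% ± 0.177 to 1.33% ± 1.12 (2.78 ± 1.03) and Mucispirillum from 1.5% ± 2.80 to 5.12% ± 3.17 (2.20 ± 0.87; 4.52 without library 5). Without library 1 the weaning means were 1.497% for Muribaculum (-3.27) and 0.610% for Parabacteroides (-3.00), and without library 11 the co-housed mean of Parasutterella was 0.374% (-3.88). The call was lost for Parasutterella without library 4 (-2.19), for Odoribacter also without library 1 or 4, for Roseburia without library 1, 2, 3, 4 or 15, and for Mucispirillum without library 1, 2, 3, 4, 13, 14 or 15. Of 71 genera 23 changed, 14 up and 9 down (30 with an unadjusted p under 0.05). DESeq2's scaling gave 8 up and 9 down, a fit to these 2 groups 11 genera, and edgeR called 15 without library 1 and 14 without library 4.

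Among 292 variants 79 changed in KO mice, 66 up and 13 down (edgeR; 130 with an unadjusted p under 0.05). NK4A136 group rows 243 (2.41% ± 2.85, at least 154-fold, 80.8-fold without library 14) and 355 (at least 13.8-fold), unclassified Lachnospiraceae row 363 (1.21% ± 1.03, at least 77.2-fold), Bacteroides row 48 (0.522% ± 0.399, at least 33.3-fold) and Prevotellaceae UCG-001 row 26 (0.209% ± 0.180, at least 13.4-fold) appeared in at least 4 of 5 co-housed KO mice. Down were Akkermansia row 4, Muribaculaceae row 108 (at least 7.72-fold), Prevotellaceae UCG-001 row 25 (-7.22 ± 1.90), Bacteroides row 44 (-6.31 ± 1.83) and unclassified Tannerellaceae row 132 (-5.71 ± 2.21). The call was lost for row 108 without library 4, for row 25 without library 1 (-4.88), and for row 132 without any one of libraries 1 to 5 and 12 to 15. The count was 33 without library 1, 42 without library 2 or 3, 36 without library 4, 45 without library 5 and 52 without library 14 or 15. It was 36 by limma-voom, 43 fitted to these 2 groups and 11 without libraries 1, 5, 11 and 19.

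Composition changed with time in both genotypes, and 6 genera rose and 3 fell in both, with 0 called in opposite directions. Time took 46.1% of the variation in composition in WT mice (exact permutation p = 0.00794, adjusted 0.0159). It took 27.1% in KO mice (exact permutation p = 0.0317, adjusted 0.0423; p was 0.0556 without library 13 and 0.0635 without library 15). Bacteroidales fell from 76.3% ± 6.09 to 36.9% ± 16.8 in WT (exact permutation, adjusted p = 0.0159) and from 61.1% ± 18.8 to 28.0% ± 13.3 in KO mice (exact permutation, adjusted p = 0.0476). Butyrate-forming Clostridia rose from 0.263% ± 0.158 to 2.94% ± 1.36 in WT (exact permutation, adjusted p = 0.0159) and from 1.19% ± 0.795 to 2.81% ± 0.921 in KO mice (exact permutation, adjusted p = 0.0476). The mucus or epithelium list rose in WT mice, from 4.42% ± 2.84 to 12.2% ± 1.99 (exact permutation, adjusted p = 0.0159), and went from 8.64% ± 5.74 to 15.6% ± 3.41 in KO mice (exact permutation, adjusted p = 0.107). Proteobacteria with Desulfobacterota fell in KO mice, from 5.96% ± 2.33 to 2.26% ± 0.748 (exact permutation, adjusted p = 0.0476), and went from 5.24% ± 3.13 to 2.58% ± 0.685 in WT mice (exact permutation, adjusted p = 0.119). Lactic acid bacteria and bifidobacteria (adjusted p = 0.0857 in WT and 0.690 in KO mice, exact permutation) and Erysipelotrichales (0.0833 and 0.248) did not pass. Expected richness rose by 82.7 variants in WT mice (exact permutation, adjusted p = 0.0318) and went up by 56.2 in KO mice (exact permutation, adjusted p = 0.0529). The Shannon index rose by 0.703 in WT mice (exact permutation, adjusted p = 0.0318) and differed by 0.116 in KO mice (exact permutation, adjusted p = 0.595). These tests of lists and diversity over time were added after the data were seen.

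**Figure D3:**
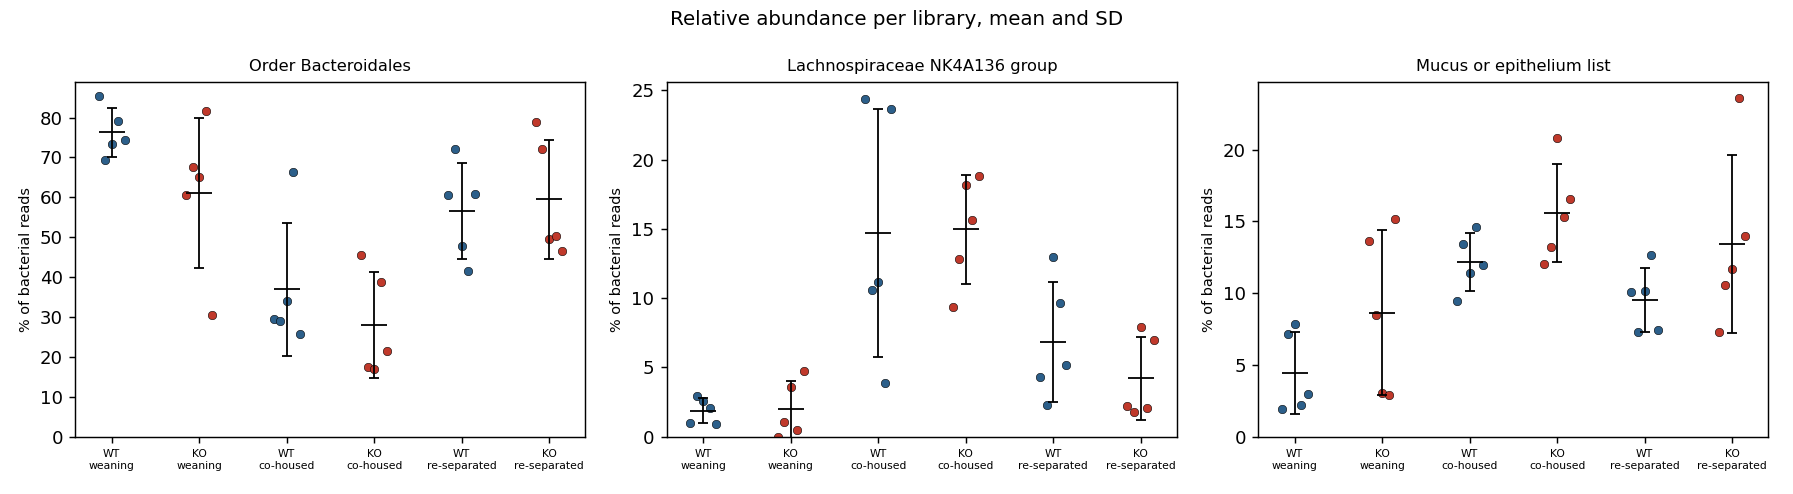
Relative abundance (percent of bacterial reads) of the order Bacteroidales, the Lachnospiraceae NK4A136 group and the mucus or epithelium list in each of the 30 libraries by genotype (KO red, WT blue) and time, with the mean and SD of each group. Bacteroidales were lower and the NK4A136 group higher after co-housing than at weaning in both genotypes; the re-separation libraries form a separate set.

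After co-housing, 3 variants and 1 genus separated the genotypes. Mucispirillum row 147 had 0 reads in KO mice and 2.07% ± 2.38 in 3 of 5 WT mice (at least 167-fold higher in WT, 94.0-fold without library 20; edgeR adjusted p = 0.00660), although the genus Mucispirillum stood at 5.12% ± 3.17 in KO and 2.82% ± 1.98 in WT mice. NK4A136 group row 295 had 0 reads in KO mice and 0.851% ± 0.660 in 4 of 5 WT mice (at least 68.7-fold higher in WT; edgeR adjusted p = 0.0185). Lachnospiraceae UCG-001 row 398 had 0 reads in KO mice and 1.08% ± 1.5 in 4 of 5 WT mice (at least 87.0-fold, 35.0-fold without library 17; edgeR adjusted p = 0.0224). All 3 variants were among those called at weaning, also with 0 reads in KO mice. The bounds at weaning were 7.02-fold for row 147, 10.8-fold for row 295 and 2.94-fold for row 398, which had reads in library 6 alone. Mycoplasma, without a cell wall, was at 19.8% ± 10.9 in KO and 10.9% ± 6.61 in WT mice and Helicobacter at 10.4% ± 1.32 and 9.32% ± 3.50. Neither genus was called.

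These 3 were the variants called of 292, all lower in KO mice (edgeR; 41 with an unadjusted p under 0.05). DESeq2 called 6, limma-voom 12 and edgeR fitted to the 2 co-housed groups alone 0 (18 with an unadjusted p under 0.05). In edgeR 1 was called without library 12, 14 or 15, and row 398 was also lost without library 11 or 17. Among 71 genera 1 was called (10 with an unadjusted p under 0.05), the [Eubacterium] siraeum group, with 0 reads in KO mice and 0.430% ± 0.842 in 2 of 5 WT mice (at least 34.8-fold, 4.56-fold without library 20; edgeR adjusted p = 0.00351). It was lost in limma-voom, in the fit to the 2 groups alone (0 genera, 3 with an unadjusted p under 0.05) and without libraries 1, 5, 11 and 19. In edgeR 4 genera were called without library 15, 3 without library 16 and 2 without library 19 or 20. UBA1819 (edgeR adjusted p = 0.0647) and the Family XIII AD3011 group (0.170) had the next smallest p and did not pass. A low count does not show that the genotypes were alike: in data simulated at the spread fitted here, the test found 2.0% of 4-fold, 7.37% of 16-fold and 58.9% of presence-or-absence changes among variants after co-housing. At weaning it found 0.75%, 7.37% and 41.8%.

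Genotype took 17.6% of the variation in composition after co-housing (exact permutation p = 0.0873, adjusted 0.0873; 0.0159 without library 14), with a separation of 0.0344 ± 0.0418 (jackknife SE). R2 was 0.1806 on Jaccard distances of presence (exact permutation p = 0.0317, unadjusted) and 0.1705 on Aitchison distances of log-ratios (exact permutation p = 0.0397, unadjusted), so the result depends on the distance. Richness was 167 ± 37.7 in KO and 218 ± 26.7 in WT mice (exact permutation p = 0.0556, adjusted 0.167; 0.0238 without library 15 and 0.0397 without library 19). The Shannon index was 3.45 ± 0.420 and 3.94 ± 0.194 (exact permutation p = 0.0794, adjusted 0.238; 0.0159 without library 14). None of the 6 lists differed by genotype, with adjusted exact permutation p from 0.476 to 0.873. The mucus or epithelium list held 1 variant lower in KO mice of 9 and the others 0. Adjusted over the list alone the counts were 1 lower in the mucus or epithelium list, 1 higher among lactic acid bacteria and bifidobacteria and 0 in the others (edgeR).

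The change in the genotype difference from weaning to co-housing was tested directly. For 18 of 292 variants the difference changed, 12 toward KO and 6 toward WT (edgeR interaction contrast; 73 with an unadjusted p under 0.05). This contrast holds the weaning libraries themselves, so chance in them favours variants that were called at weaning. Bacteroides row 48 went from 0 reads to 0.522% ± 0.399 in KO mice while it went from 2.43% ± 2.10 to 0.313% ± 0.404 in WT mice (edgeR adjusted p = 0.00126). Alistipes row 137 went from 0 reads to 0.639% ± 0.912 in KO mice, with reads in 2 of 5 (0.309% without library 14), and from 1.26% ± 1.06 to 1.07% ± 0.464 in WT mice. NK4A136 group row 291 went from 0 reads to 2.16% ± 3.23 in KO mice, with reads in 2 of 5 (0.884% without library 13), and from 0.372% ± 0.319 to 0.0383% ± 0.0856 in WT mice. Muribaculaceae row 60 went the other way, from 0.627% ± 0.697 to 0.146% ± 0.146 in KO mice and from 0 reads to 0.523% ± 0.422 in WT mice (edgeR adjusted p = 0.00521). So did Gastranaerophilales row 168, from 1.88% ± 1.80 to 0.116% ± 0.159 in KO mice and from 0 reads to 0.159% ± 0.287 in WT mice. These 5 rows were still called with any one of the 20 libraries left out. The log2 change then lay between 13.07 and 14.67 for row 48, 10.0 and 11.11 for row 137, 14.40 and 22.58 for row 291, -13.21 and -11.67 for row 60, and -12.98 and -9.66 for row 168. Each of these rows had 0 reads in a genotype at weaning. The size of these changes is thus not measured, and only their direction can be read. The genera that passed were Clostridia UCG-014, unclassified Erysipelotrichaceae and Ureaplasma, 3 of 71 (16 with an unadjusted p under 0.05), all moved toward KO. Genera with 0 reads in both genotypes at a time, or at both times in a genotype, gave this contrast no usable estimate. Among them was Akkermansia, called at weaning and at 0 reads in both genotypes after co-housing (-8.34, SE 1.578e+04). The same limit holds in the other interactions of genera. Ureaplasma went from 0.349% ± 0.210 to 1.08% ± 2.07 in KO mice and from 1.36% ± 1.13 to 0.202% ± 0.134 in WT mice. Library 11 held 4.77% and the other 4 co-housed KO libraries at most 0.263%, and without library 11 the change fell from 4.84 to 2.15 and was not called. Clostridia UCG-014 went from 0 reads to 0.185% ± 0.346 in KO mice (0.0313% without library 14, still called) and from 0.15% ± 0.157 to 0.0923% ± 0.0440 in WT mice. Unclassified Erysipelotrichaceae went from 0 reads to 0.134% ± 0.209 in KO mice (0.0454% without library 11, still called) and from 0.0505% ± 0.0365 to 0.0136% ± 0.0304, in library 16 alone, in WT mice.

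The variant count was 8 without library 1, 11 without library 4 or 17, and 8 by limma-voom and without libraries 1, 5, 11 and 19. For genera, library size in place of the composition-corrected scaling gave 3 toward KO and 1 toward WT with the median moved by -0.70, and DESeq2 and the table without a filter called 8. In edgeR the genus count was 8 without library 4, 6 or 12, 7 without library 19, 6 without library 8, 10 or 13 and 1 without libraries 1, 5, 11 and 19. The interaction took 5.97% of the variation in composition (permutation p = 0.0799, adjusted 0.120; p was 0.0494 without library 4, 0.0482 without library 5 and 0.0452 without library 19). It took 6.55% on Jaccard (permutation p = 0.00556, unadjusted) and 6.70% on Aitchison distances (permutation p = 0.00787, unadjusted).

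Variants found in at least 3 mice of one genotype and in 0 of the other at weaning were followed into the co-housed mice. There were 54, 19 restricted to KO and 35 to WT mice, among them 9 and 12 Lachnospiraceae. After co-housing, 5 of the 19 were found in at least 3 WT mice and 15 of the 35 in at least 3 KO mice, 37.0% together (95% exact binomial interval 24.3 to 51.3). The interval counts the 54 variants as independent, though the same mice hold them, so it does not cover the spread between mice. These variants were chosen for 0 detections in the other genotype at weaning, so chance can only add detections there later. Expected richness also went up, by 82.7 variants in WT and 56.2 in KO mice. With no mice kept apart as a baseline, the 37.0% does not measure transfer between genotypes. Odoribacter row 126, restricted to WT at weaning, was in 5 of 5 mice of each genotype after co-housing, and Bacteroides row 48 in 4 KO and 3 WT mice. Muribaculaceae row 60, restricted to KO at weaning, was in 5 of 5 co-housed WT mice and in 4 KO mice, and Blautia row 371 in 5 of 5 of each. Akkermansia row 4, restricted to KO at weaning at this depth, was in no co-housed mouse of either genotype. The 5 variants named here were chosen after their values were seen. Of the restricted variants 7 of the 19 were still in at least 3 KO mice and 29 of the 35 in at least 3 WT mice.

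A score of the weaning difference still separated the genotypes after co-housing. It set the log-ratio abundance of the 20 variants higher in KO at weaning against that of the 41 lower ones, and differed between the genotypes by 9.38 at weaning. After co-housing it was -0.0960 ± 2.32 in KO and -3.36 ± 1.53 in WT mice, a difference of 3.26 (SD, n = 5; exact permutation p = 0.0317). The p was 0.0556 without library 12 or 17, 0.0714 without library 18 or 20 and 0.0635 without library 19.

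After re-separation, NK4A136 group row 1177 had 0 reads in KO mice and 1.02% ± 0.689 in WT mice (at least 202-fold higher in WT; edgeR adjusted p = 0.00119). Row 1241 of the same group had 0 reads and 0.0596% ± 0.0330 (at least 11.8-fold; edgeR adjusted p = 0.0283). ASF356 row 1061, a Lachnospiraceae variant, was at 0.109% ± 0.0548 in 5 of 5 KO mice and had 0 reads in WT mice (at least 19.0-fold higher in KO; edgeR adjusted p = 0.0105). Dubosiella row 1693, of the Erysipelotrichaceae, was at 0.0591% ± 0.0476 in KO mice with 0 reads in WT mice (at least 10.3-fold, 6.79-fold without library 24; edgeR adjusted p = 0.0401). The genus Dubosiella was in 5 of 5 WT mice too, at 0.0185% ± 0.0127. The genus ASF356 was at 0.181% ± 0.104 in KO and 0.142% ± 0.0826 in WT mice. Neither genus was called. These 4 were the variants called of 278, 2 higher and 2 lower in KO mice (29 with an unadjusted p under 0.05). DESeq2 called 16 and limma-voom 23. The call of Dubosiella row 1693 was lost without library 21, 22, 23, 24 or any of 26 to 30 and that of row 1241 without any of 26 to 30. In all, 2 were called without library 27, 28 or 30 and 16 were called without library 25.

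Of 71 genera 0 differed after re-separation (edgeR; 6 with an unadjusted p under 0.05; DESeq2 0, limma-voom 1). Candidatus Stoquefichus, at 0.0208% ± 0.0372 in KO mice with 0 reads in WT mice (edgeR adjusted p = 0.110), UBA1819, with 0 reads in KO and 0.0195% ± 0.0120 in WT mice (edgeR adjusted p = 0.110), and Lachnospiraceae UCG-004 (edgeR adjusted p = 0.129) had the smallest p and did not pass. Erysipelotrichales, the order of Dubosiella, were higher in KO mice at 0.141% ± 0.0787 against 0.0317% ± 0.0182 (SD, n = 5; exact permutation p = 0.00794, adjusted over the 6 lists 0.0476), with 1 of 2 variants higher and 2 higher adjusted over the list alone (edgeR). It was the one list that passed at any of the 3 times with all libraries. Without any one of the WT libraries 26 to 30 the difference, 0.109, became 0.104 to 0.114, but the list did not pass (exact permutation p from 0.0317 to 0.0476, adjusted 0.190 to 0.286). With 9 libraries the 126 orderings let a list pass alone only at the smallest p. The other 5 lists had adjusted exact permutation p from 0.417 to 0.754, with 0 variants called in each, also adjusted over the list alone. Bacteroidales were at 59.5% ± 14.9 in KO and 56.6% ± 12.0 in WT mice, and Helicobacter at 12.2% ± 5.81 and 8.45% ± 1.58.

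Genotype took 19.4% of the variation in composition after re-separation (exact permutation p = 0.0714, adjusted 0.0873; 0.0317 without library 25), with a separation of 0.0297 ± 0.0274. R2 was 0.2535 on Jaccard and 0.2446 on Aitchison distances (exact permutation p = 0.00794 for each, unadjusted), so this result too depends on the distance. Richness was 218 ± 33.3 in KO and 248 ± 27.8 in WT mice (exact permutation p = 0.167; 0.0159 without library 25). The Shannon index was 3.77 ± 0.339 and 3.86 ± 0.134 (exact permutation p = 0.595; the difference turned to 0.00920 without library 24).

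From weaning to re-separation, the genotype difference changed for 13 of 71 genera, 10 toward KO and 3 toward WT (edgeR; 20 with an unadjusted p under 0.05). Here too the weaning libraries enter the contrast, and chance in them favours genera that were called at weaning. The Rikenellaceae RC9 gut group went from 0.0349% ± 0.0353 to 1.35% ± 0.797 in KO mice and from 1.00% ± 0.484 to 1.19% ± 0.673 in WT mice, a change in the genotype difference of 5.70 ± 1.35 on the log2 scale (edgeR adjusted p = 0.00570). Gastranaerophilales went from 2.40% ± 1.69 to 1.30% ± 0.682 in KO mice and from 0.162% ± 0.209 to 3.15% ± 2.97 in WT mice (-4.15 ± 1.29). Blautia went from 0.347% ± 0.540 to 0.0729% ± 0.0566 in KO mice and from 0.00596% ± 0.0133 to 0.109% ± 0.0278 in WT mice (-5.67 ± 1.71). Akkermansia went from 1.54% ± 2.35 to 0.00992% ± 0.00706 in KO mice with 0.00136% ± 0.00304 in WT mice (-5.77 ± 2.00). Unclassified Erysipelotrichaceae, RF39, Clostridia UCG-014 and the NK4A214 group, all at 0 reads in KO mice at weaning, had reads in 5 of 5 KO mice after re-separation. These libraries are deeper, and levels of RF39 (0.00353% and 0.00646%) and unclassified Erysipelotrichaceae (0.00786%) in some of them lie under the floor of every KO library at weaning, so depth adds to this count. The call was lost for Gastranaerophilales without library 1 or 30, for Blautia without library 1, and for Akkermansia without library 1, 2, 6, 7, 8, 9, 21, 22, 24, 25 or 26. With library size in place of the composition-corrected scaling 6 moved toward KO and 4 toward WT and the median moved by -0.90. The count was 6 without library 1 and 8 without library 8, 21, 24 or 26.

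From co-housing to re-separation the difference changed for 0 of 71 genera (edgeR; 5 with an unadjusted p under 0.05; DESeq2 1, limma-voom 0; 1 in edgeR without library 15). Akkermansia, at 0 reads in both genotypes after co-housing, gave no usable estimate here (SE 5322). The genus-based carry-over score of weaning differences was -0.923 ± 1.09 in KO and -1.66 ± 0.568 in WT mice (exact permutation p = 0.214). Of 16 full taxon names restricted to 1 genotype at weaning 12 were found in the other after re-separation: 3 of 6 from KO and 9 of 10 from WT, 75.0% (95% exact binomial interval 47.6 to 92.7). A name can pool several variants, so this share cannot be set beside that of variants after co-housing. The interval counts names as independent and does not cover the spread between mice. Names were chosen for 0 detections in the other genotype at weaning, so chance can only add detections there later. The 75.0% thus does not measure transfer between genotypes. In composition the genotype difference changed from co-housing to re-separation with 4.56% of the variation (permutation p = 0.244, adjusted 0.244) and from weaning to re-separation with 9.37% (permutation p = 0.0775, adjusted 0.120; p was 0.0161 without library 4). The change from weaning to re-separation took 6.93% on Jaccard (permutation p = 0.00773, unadjusted) and 8.10% on Aitchison distances (permutation p = 0.00027, unadjusted).

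Re-separation was compared with co-housing within each genotype, and here the set of libraries and the time cannot be told apart. Unnamed Muribaculaceae stood at 7.25% ± 2.59 after co-housing and 28.7% ± 10.4 after re-separation in KO mice (log2 fold change 2.56 ± 0.62; edgeR adjusted p = 0.00412). Parabacteroides was at 0.0886% ± 0.0498 and 0.874% ± 0.326 (3.76 ± 1.02), the Rikenellaceae RC9 gut group at 0.176% ± 0.186 and 1.35% ± 0.797 (3.32 ± 0.97), and Muribaculum at 0.238% ± 0.0886 and 1.07% ± 0.245 (2.73 ± 0.85). Akkermansia had 0 reads in co-housed KO mice and was at 0.00992% ± 0.00706 in 4 of 5 re-separated KO mice (edgeR adjusted p = 0.0265), a level too low for a bound on the fold. Unclassified Oscillospiraceae were lower, at 3.01% ± 2.66 and 0.429% ± 0.368 (-2.51 ± 0.80), as was Roseburia, at 1.33% ± 1.12 and 0.156% ± 0.123 (-2.76 ± 1.03). The call was lost for Muribaculum and Akkermansia without library 12, 13 or 21, for unclassified Oscillospiraceae without library 12 (1.86% in the other co-housed mice, -1.94), 21, 22 or 24, and for Roseburia without any of 12 to 15 and 21 to 25. Pseudomonas, also found in reagents, went from 0.139% ± 0.104 in KO (at least 27.6-fold) and 0.0783% in WT mice (at least 13.7-fold; edgeR adjusted p = 0.00256) to 0 reads.

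Of 71 genera 15 were called in KO mice, 11 up and 4 down (24 with an unadjusted p under 0.05), and 1, Pseudomonas, in WT mice (9 with an unadjusted p under 0.05). For KO mice library size gave 5 up and 3 down with the median moved by -0.35 and DESeq2's scaling 8 up and 1 down with the median moved by 0.29. In edgeR 6 genera were called without library 12 or 13, 5 without library 21, 8 without library 22 and 9 without library 24. For WT mice DESeq2's scaling moved the median by 0.49 and gave 1 up and 1 down. DESeq2 and limma-voom each called 3, a fit to these 2 groups 6 and edgeR without libraries 1, 5, 11 and 19 called 12. In composition of genera, time took 50.3% of the variation in KO mice (exact permutation p = 0.00794, adjusted 0.0159) and 28.2% in WT mice (exact permutation p = 0.0714, adjusted 0.0714; 0.0159 without library 19).

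Reads that do not come from gut bacteria were few. Mitochondrial reads were at 0.166% ± 0.274 in KO and 0.0332% ± 0.0235 in WT mice at weaning (exact permutation p = 0.270). They were at 0.435% ± 0.276 and 0.608% ± 0.317 after co-housing (exact permutation p = 0.341) and 0.0924% ± 0.0791 and 0.161% ± 0.126 after re-separation (exact permutation p = 0.349), all with adjusted p of 1. Genera common in reagents, such as Pseudomonas, were at 0.0851% ± 0.0553 and 0.0275% ± 0.0387 at weaning (exact permutation p = 0.135), at 0.181% ± 0.145 and 0.0863% ± 0.0436 after co-housing (exact permutation p = 0.206) and at 0 reads after re-separation. Chloroplast, reads with no kingdom, and the skin genera Staphylococcus, Cutibacterium and Corynebacterium had 0 reads in all 30 libraries.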

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

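The counts of calls in other groupings of the libraries were tests chosen only after the counts were seen; the same is true of the test of exchanged labels on variants gained in co-housing; the tests of depth, of left-out libraries, of exchanged labels on restricted variants and of separate processing were chosen before their own results were seen, but after the patterns they address.

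Samples far from the others of their group were looked for in 174 groups of 5 values, and 19 stood out by more than the 95% limit for the gap over the range (0.710). Chance marks about 1 in 20 groups, which is 8.7 here. Library 19, from a co-housed WT mouse, accounted for 7 of them: Bacteroidales 66.37% (next highest in the group 34.11%), family Muribaculaceae 26.46% (9.482%), genus Muribaculaceae 25.48% (9.228%), Bacteroidaceae, all Bacteroides, 6.811% (1.843%), and Sutterellaceae, all Parasutterella, 1.228% (0.4434%). Library 5, from a KO mouse at weaning, had 0.6534% of mitochondrial reads (next 0.07093%) and 6.501% Mucispirillum, the one genus of Deferribacteraceae (next 0.4347%). Library 1, also KO at weaning, had the fewest variants, 52.92 expected at equal depth against 113 in the next. Library 11, a co-housed KO mouse, had 2.968% Bacteroides (next 1.016%), library 9, WT at weaning, 15.04% Bacteroides (next 6.535%), and library 4, KO at weaning, 0.08757% Erysipelotrichales where the other 4 had 0 reads. After re-separation, library 24 (KO) had 0.4151% of lactic acid bacteria and bifidobacteria (next 0.1558%), library 26 (WT) 3.456% Rikenellaceae (next lowest 6.939%) and library 29 (WT) 3.395% Oscillospiraceae (next 2.091%). The genotype difference itself changed between weaning and co-housing for 18 variants and 3 genera, and between weaning and re-separation for 13 genera. Outside the bacterial comparisons, 2467 reads were mitochondrial, and these lie in all 3 times.

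The first pattern weighed is that 61 variants differed by genotype at weaning and 3 after co-housing, 2 counts whose difference is tested in part by the 18 interactions. Unequal depth is argued against, since 50 variants were called at weaning, and 2 after co-housing, with all libraries thinned to the smallest. A count made by libraries 1 and 5 alone is argued against too: without them 14 variants were called, and leaving out each of the other 9 pairs of KO weaning libraries left 7 to 21. Shared litters or cages at weaning stay open, because the labels do not give them, as does an effect of genotype that co-housing removes. So does a change with age, since no mice kept apart over the same weeks were sampled. In simulated data the test found 58.9% of presence-or-absence changes after co-housing and 41.8% at weaning, and many differences were missed at both times. The simulation gave each variant the same spread at both times, so it cannot show power lost to a larger spread after co-housing. Mean distances within groups were 0.315 at weaning and 0.450 after co-housing in WT mice, and 0.575 and 0.506 in KO mice. Whether power fell after co-housing thus stays open.

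The second pattern is that libraries 5, 11 and 19 lay nearer to the libraries of the other time point than to those of their own, by mean distances of 0.1365, 0.05733 and 0.1131. Shallow sequencing is argued against, since after thinning all 3 stayed nearer to the other time, the lowest by 0.05812. An exchange of the labels of libraries 5 and 11 is argued against as well. Of 36 variants found in at least 3 of the other 4 co-housed KO mice and in none of the other 4 KO mice at weaning, library 11 held 38.89% and library 5 held 5.556% (exact binomial p = 0.00418), the order the labels give. This p counts variants of the same libraries as independent, so it does not measure the spread between mice. Akkermansia was at 0.2097% in library 5, as in all KO mice at weaning, and had 0 reads in library 11. The variants restricted at weaning did not decide: library 11 held 38.46% of those restricted to KO, defined without library 5, and 36.11% of those restricted to WT (Fisher's exact p = 1). Mitochondrial reads lay the other way: library 5 held 0.6534%, and libraries 11 and 19 held 0.03925% and 0.0687%. The other weaning libraries held at most 0.07093%, and the other co-housed libraries at least 0.2546%. A mix-up that involves library 19 was not tested and stays open. A mouse that took up or kept the bacteria of the other time also remains open as an untested biological explanation.

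The third pattern is that no variant had reads both in the re-separation libraries and in the others. Separate denoising or classification of the 2 sets is a candidate explanation: 89.16% of the full taxon names with reads in the re-separation set (148 of 166) also had reads, under other variants, in the other set. The bacteria named are thus largely the same, and the absence of shared variants may say nothing about the mice. Changes of relative abundance between the sets cannot be told apart from it.

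The libraries were also regrouped at random, 100 groupings for each count with the real one included, and the number of groupings that called as many is given with the real count and the highest of the others. For variants, chance is argued against for genotype at weaning (1 of 100, 61 against 5). The same holds for time in WT (1 of 100, 2 against 1) and KO mice (1 of 100, 79 against 53). It holds less firmly for genotype after re-separation (2 of 100, real count 4, highest other 4). For the interaction of weaning and co-housing, 2 of 100 groupings called as many (real count 18, highest other 26). Chance cannot be excluded for genotype after co-housing (12 of 100, real count 3, highest other 6). For genera, chance is argued against for genotype at weaning (1 of 100, 17 against 10). The same holds for weaning to co-housing in WT (1 of 100, 21 against 17) and co-housing to re-separation in KO mice (1 of 100, 15 against 2). It holds less firmly for weaning to co-housing in KO mice (2 of 100, real count 23, highest other 26). So it does for co-housing to re-separation in WT mice (2 of 100, real count 1, highest other 3). For the interaction of weaning and re-separation, 1 of 100 groupings called as many (13 against 12). Chance cannot be excluded for genera by genotype after co-housing (56 of 100, real count 1, highest other 3) and after re-separation (100 of 100, 0 against 1). Nor can it for the interaction of weaning and co-housing (14 of 100, real count 3, highest other 16). The same is true of the interaction of co-housing and re-separation (100 of 100, 0 against 3). Where 2 of 100 groupings called as many, 1 random grouping did so too, so those results are weaker. The 16 counts were not adjusted for their number. Regrouping moves single mice, so it cannot argue against a chance difference between cages or litters, which the labels do not give. Regrouping removes the genotype difference itself as well as its change between times. For an interaction, a count that few regroupings reach thus does not exclude chance for the change.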

How the results depend on the processing

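Leaving out libraries 1, 5, 11 and 19 together, and every alternative for genera from weaning to co-housing and in the interaction of weaning and co-housing, were tests chosen only after results were seen. The alternatives for comparisons that reach from one set of libraries into the other were planned for variants and moved to genera after the data were seen, and the remaining ones were planned. Of 662 alternative values for 38 results, 524 kept their direction and side of the threshold or stayed within 1.5 times the count, and 7 results did so in all. Weighted UniFrac was not run, since the table has no sequences. No paired analysis was possible because the libraries carry no shared numbers across groups. For the changed values that follow, the cause was not tested, except that fewer libraries or groups in a fit leave fewer degrees of freedom.

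Library size as scaling called 4 variants in WT from weaning to co-housing (main 2), 26 genera by genotype at weaning (17), 32 genera in WT from weaning to co-housing (21) and 8 genera in KO from co-housing to re-separation (15). DESeq2's scaling called 2 genera in WT (1) and 9 in KO (15) from co-housing to re-separation. DESeq2 called 6 variants by genotype after co-housing (3), 16 after re-separation (4), 33 in WT from weaning to co-housing (2), 8 genera in the interaction of weaning and co-housing (3), 1 in that of co-housing and re-separation (0) and 3 in WT from co-housing to re-separation (1). limma-voom called 37 variants by genotype at weaning (61), 12 after co-housing, 23 after re-separation, 8 in the interaction of weaning and co-housing (18), 57 in WT and 36 in KO from weaning to co-housing (2 and 79), 2 genera by genotype after co-housing (1), 1 after re-separation (0) and 3 in WT from co-housing to re-separation. Without a filter there were 5 variants by genotype after co-housing, 9 in WT from weaning to co-housing, and 8 and 1 genera in the interactions of weaning with co-housing and of co-housing with re-separation. The filter of 5 libraries gave 4 variants in WT from weaning to co-housing. Fits of only the groups compared called 0 variants (18 with an unadjusted p under 0.05) and 0 genera (3) by genotype after co-housing in edgeR, 32 variants in WT and 43 in KO from weaning to co-housing, 8 genera by genotype at weaning, 11 genera in KO from weaning to co-housing and 6 in WT from co-housing to re-separation.

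Without libraries 1, 5, 11 and 19 there were 15 variants by genotype at weaning, 8 in the interaction of weaning and co-housing, 22 in WT and 11 in KO from weaning to co-housing, 0 genera by genotype after co-housing, 1 in the interaction of weaning and co-housing, 36 in WT from weaning to co-housing and 12 in WT from co-housing to re-separation. R2 of WT composition from co-housing to re-separation became 0.5151 (exact permutation p = 0.0159) and the interaction of weaning and co-housing took 6.462% (permutation p = 0.0315).

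For composition, family sums lowered the genotype R2 at weaning to 0.1598 (exact permutation p = 0.190). Jaccard distances raised R2 after co-housing to 0.1806 (exact permutation p = 0.0317), after re-separation to 0.2535 (0.00794) and gave 0.2597 (0.00794) in WT from co-housing to re-separation, with interactions of 6.551% (permutation p = 0.00556) for weaning and co-housing and 6.933% (0.00773) for weaning and re-separation. Aitchison distances gave 0.1705 (exact permutation p = 0.0397), 0.2446 (0.00794), 0.2744 (0.00794), 6.704% (0.00787) and 8.099% (0.00027) in the same order. Richness without variants of a single library differed by -51.27 after co-housing (exact permutation p = 0.0317). The inverse Simpson index differed by 3.099 at weaning (exact permutation p = 0.00794) and, reversed against the Shannon index, by 2.219 after re-separation (exact permutation p = 0.484).

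Leaving out 1 library at a time gave, for variants, 27 to 52 by genotype at weaning, 1 to 4 after co-housing, 2 to 16 after re-separation, 8 to 26 in the interaction, and 0 to 12 in WT and 33 to 82 in KO from weaning to co-housing. For genera it gave 1 to 4 by genotype after co-housing, 3 to 8, 0 to 1 and 6 to 15 in the interactions of weaning and co-housing, co-housing and re-separation, and weaning and re-separation, 16 to 34 in WT and 14 to 28 in KO from weaning to co-housing and 5 to 15 in KO from co-housing to re-separation. R2 ranged over 0.1585 to 0.2326 after co-housing, 0.1712 to 0.2501 after re-separation, 0.2344 to 0.5151 in WT from co-housing to re-separation and 0.2396 to 0.3528 in KO from weaning to co-housing, and the interactions over 5.446% to 6.944% and 7.95% to 14.14%. Differences ranged over -61.88 to -38.28 and -44.12 to -18.78 in richness after co-housing and re-separation, -0.6282 to -0.399 and -0.1939 to 0.009196 (reversed without library 24) in the Shannon index and 2.41 to 3.93 in carry-over after co-housing, and 0 to 4 lists passed. Depth limits what an absence shows: for a group at 0 reads the floor is 3 counts in each of its libraries.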

Other observations

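No explanation is offered for the values given here. The phyla were not tested as such, but to the digits given Bacteroidota have the group values of the order Bacteroidales, which was tested at each time. The 3 genera named were among the 71 tested and were called in no contrast, with edgeR adjusted p of at least 0.133 for Alistipes, 0.0844 for Alloprevotella and 0.178 for unclassified Desulfovibrionaceae. At the level of phyla, Bacteroidota held 61.1% ± 18.8 of bacterial reads in KO and 76.3% ± 6.09 in WT mice at weaning, 28.0% ± 13.3 and 36.9% ± 16.8 after co-housing, and 59.5% ± 14.9 and 56.6% ± 12.0 after re-separation (SD, n = 5). Firmicutes held 21.7% ± 15.9 and 13.9% ± 6.21, 53.1% ± 11.5 and 47.4% ± 17.8, and 22.3% ± 12.3 and 27.7% ± 11.0 in the same groups. Among members of the Bacteroidales list, Alistipes, which tolerates bile, had group means between 2.91% ± 0.922 in co-housed KO and 5.08% ± 1.83 in re-separated WT mice. Alloprevotella was at 1.55% ± 0.882 in KO and 1.36% ± 0.953 in WT mice at weaning and at 1.29% ± 1.04 and 1.76% ± 1.68 after re-separation. Unclassified Desulfovibrionaceae, sulfate reducers of the list of Proteobacteria with Desulfobacterota, reached 1.34% ± 1.65 in KO mice at weaning and 1.25% ± 0.892 in WT mice after co-housing.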
